A study of Mus musculus with 22 samples.

How the data were processed

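RNA of 22 samples of mouse embryonic germ (EG) and embryonic stem (ES) cell lines was measured on Affymetrix mouse gene arrays, with 1 array per sample. Per the labels, the arrays fall into 5 groups: EG lines in fetal calf serum (FCS), EG lines started in FCS and moved to 2i after 48 hours (2is), EG lines derived directly in 2i, ES lines in FCS and ES lines in 2i. For ES 2i line 5 the cell-type label reads EGCs while its title and source name say ES, and it was analysed as an ES line. Without it 5670 genes were called for ES 2i against FCS, 599 for EG 2i against ES 2i, 7 for EG 2is against ES 2i and 178 for the difference between the EG and ES responses. FCS medium contained leukaemia inhibitory factor (LIF), and the cells lay on a mouse embryonic fibroblast feeder layer. 2i medium was N2B27 with the MEK inhibitor PD0325901, the GSK3 inhibitor CHIR99021 and LIF, and those cells lay on laminin. Feeder layer and culture medium therefore changed together. Replicates are separately labelled samples, each called a line here, and whether ES samples of the same number in FCS and 2i are the same line is not known. The labels say nothing more about separate cultures, so the p-values measure the spread between these samples.

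The deposited values are log2 RMA expression values, 1 per probe set and array. The submitters' processing notes name Affymetrix Expression Console, RMA and limma, with versions not given in the sources used here. RMA corrects the background, normalizes by quantiles and summarizes the probes of a probe set. A batch adjustment by the authors is not stated. The values ran from 3.63 to 13.9, and array medians lay between 5.5 and 5.6. No pair of arrays was identical (0 of the pairs), and arrays of the same group correlated at 0.982 to 0.998. The number of arrays limits the precision of every value given here.

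The value table held 28853 probe sets, of which 21789 were listed with a single gene symbol, 1621 with several and 5443 with none. Symbols were matched by Entrez ID to a table of mouse genes of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. It held 21698 of the probe sets with 1 symbol, and 0 symbols needed an update. Each gene was represented by its probe set with the highest mean over all arrays, which left out 1851 second probe sets and gave 19938 genes. Of these 739 were X-linked, 9 Y-linked and 19106 autosomal, and 82 had no chromosome in the table. Probe sets without a single gene were tested separately and are reported only as counts.

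All 22 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), with a term for each group, the labelled batch and the labelled sex. Batch 1 held 16 arrays, among them all EG arrays, and batch 2 held 6, all of them ES lines in both cultures. The batch term therefore rests on ES lines alone and cannot be told apart from differences between those lines. Fitted differences between EG and ES lines of the same culture depend on it. For sex, the terms were the groups, the batch and a sex term in each culture (FCS, or any 2i). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a gene comes from limma and is two-sided. Values of groups are means with the standard deviation (SD), fold changes carry limma's standard error (SE) on the log2 scale, and n is the number of samples. Single values per line were compared by two-sided exact permutation tests. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 was used for permutation tests and correlations, and matplotlib 3.10.9 for the figures.

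Comparisons, covariates, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For EG 2i against FCS and ES 2i against FCS the rule names the 6 largest rises and the 6 largest falls among called genes whose groups overlap in no array, and up to 3 members of each list with the smallest adjusted p. For every other comparison it names the 4 largest in each direction and up to 2 called members of each list. Predicted genes without a described name are counted but passed over. Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Tet1, Tet2, Tet3, Prdm14, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Dazl and Xist are always included.

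The gene lists were DNA methyltransferases, TET and demethylation, core pluripotency, naive pluripotency factors, primed epiblast, primitive streak and mesoderm, neural ectoderm, primitive endoderm, trophoblast, methylation-dependent germline genes, primordial germ cell, ERK targets, Wnt targets, BMP-SMAD targets, LIF-STAT3 targets, feeder fibroblast markers, cholesterol synthesis, Polycomb, imprinted genes, two-cell-like, glycolysis, proliferation, housekeeping, X inactivation centre, Y-linked genes and all X-linked genes. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over all lists of a comparison. Members are counted by the adjusted p over all genes, and again adjusted over the list alone. Members without a probe set of their own were not tested, among them Tdg, T, H19, Snrpn and Gapdh.

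The X dosage of a line is the median log2 level of X-linked genes minus that of autosomal genes, over the genes whose mean lies above the 60th percentile (269 X-linked and 7695 autosomal genes). The spread of a culture is the root mean square deviation of a line from its group, after removal of batch and sex terms.

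The fit was tested on simulated data, drawn once per comparison and independently for each gene and array from the real means and residual spreads. In them 200 of 19938 genes were changed by known amounts. No correlation between genes or structure among lines was simulated, so the false shares below need not hold for the real arrays. For EG 2i against FCS, 67.2% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 98.5% of changes of 2 were recovered, and 7.37% of the called genes were false. For ES 2i against FCS the shares were 74.6%, 98.5% and 100%, with 3.19% false. For EG 2i against ES 2i they were 68.7%, 98.5% and 97.0%, with 4.86% false. For the difference between the EG and ES responses they were 46.3%, 89.6% and 100%, with 5.99% false.

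Most alternatives changed 1 choice at a time, but batch and sex terms were also left out together, and the replicate block took the place of batch in fits of the compared groups alone. The choices were the batch and sex terms, the array run in place of batch, a replicate block, the groups in the fit, the prior, the normalization, filters at the 20th and 40th percentile of the mean level, the probe sets of a gene, a 2-fold minimum, single sexes or batches, and each line left out in turn. Others were chosen after seeing the data: X dosage in place of sex, lines of low X dosage left out, ES lines 4 and 5 averaged, single array runs, batch 1 alone for EG against ES, the feeder marker level as a term, a replicate block for ES lines alone in the fit of all arrays, and the spread without the batch or the sex term. Where groups of at least 3 lines were compared, the arrays were regrouped in every other way, or in 100 drawn ways where there were more. Raw scans were not analysed here.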

Results

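Genome-wide mRNA levels were measured in 22 samples. EG lines were 4 in FCS (1 female), 4 moved from FCS to 2i (2is, 2 female) and 4 derived in 2i (3 female). ES lines were 5 in FCS and 5 in 2i (2 female each). EG cells are pluripotent lines derived from the primordial germ cells of embryos, and ES cells are derived from early embryos before implantation. Per the series text, lines came from genetically identical embryos, and ES lines were also switched between the cultures once established. Some ES samples in FCS and 2i can therefore be the same line. The design asks how 2i culture and cell origin relate to gene expression. Culture was the main axis of the data: the first principal component held 53.1% of the variance, with FCS lines between −39.8 and −24.3 and 2i lines between 14.3 and 29.5. As a measure of background, the Y-linked gene Eif2s3y was at 4.73 ± 0.08 (SD, n = 10) in female and 8.35 ± 0.36 (SD, n = 12) in male lines on the log2 scale, and 23.7% of genes had a mean below its highest female level of 4.88. Where a group mean lies below that level the size of a change is limited by background, as for Egr1 in 2i lines, Gadd45g and Tagln in EG 2i lines, Nnat in ES 2i lines and Dmgdh in ES FCS lines. No sex label conflicted with Eif2s3y or Uty (0 lines).

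In EG lines the change from FCS to 2i was large. More EG 2i than EG FCS lines were female, and 1 sex term served all cultures, so part of the change can come from sex. Acta2, smooth muscle actin of contractile cells, fell by 4.5 on the log2 scale (SE 0.31, 22.6-fold, adjusted p = 9.6e-09, n = 4 and 4). Dnmt3l, the cofactor of the de novo DNA methyltransferases, fell by 4.44 (SE 0.53, 21.7-fold, adjusted p = 6.0e-06). Crxos, a homeobox gene, rose by 3.55 (SE 0.34, 11.7-fold, adjusted p = 4.9e-07), and Aqp3, a water and glycerol channel, rose by 3.22 (SE 0.39, 9.29-fold, adjusted p = 7.7e-06). Other large rises were those of Bhmt, an enzyme of methionine synthesis from betaine (7.95-fold), Ppp1r14d, a phosphatase inhibitor (7.75-fold), Dazl, an RNA-binding protein of germ cells (6.47-fold), and Calcoco2, an autophagy receptor (6.06-fold). Large falls included Thbs1, a matrix protein (19-fold), Enpp3, an ectonucleotidase (16.7-fold), Lefty1, a Nodal antagonist (16.6-fold), and the imprinted gene Peg10 (15.2-fold). In each of these genes every EG 2i line lay beyond every EG FCS line. In total 4764 of 19938 genes were called, 2274 higher and 2490 lower in 2i, 631 of them by at least 2-fold.

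Genes of DNA methylation moved apart from one another in EG lines. The de novo methyltransferase genes fell: Dnmt3a by 1.42 (SE 0.32, adjusted p = 0.00279) and Dnmt3b by 1.95 (SE 0.26, adjusted p = 1.8e-05), beside their cofactor Dnmt3l. The maintenance methyltransferase Dnmt1 differed by −0.12 (adjusted p = 0.266), and its recruiting factor Uhrf1 rose by 0.23 (adjusted p = 0.0384), a call that ended when arrays were centred on their medians (adjusted p = 0.0689) and without any 1 of EG FCS lines 2, 3 and 4 or EG 2i lines 1 and 4 (adjusted p = 0.0707 to 0.114). Of 7 genes in the DNA methyltransferase list 1 rose and 4 fell (2 and 4 adjusted over the list alone). The list as a whole was lower (adjusted p = 0.0444, and adjusted p = 0.258 with an estimated correlation), but not after quantile normalization again (adjusted p = 0.0886), after centring (adjusted p = 0.0648), or without any 1 of EG FCS lines 1 and 2 and EG 2i lines 2 and 3 (adjusted p = 0.0592 to 0.0723). Among 12 genes of the TET and demethylation list 3 rose and 4 fell (5 and 4 adjusted over the list alone). Tet1, an oxidase of 5-methylcytosine, fell by 0.72 (SE 0.11, adjusted p = 1.2e-04), the stress-response genes Gadd45g and Gadd45a fell by 3.16 and 1.91, while Tet2 differed by 0.56 (adjusted p = 0.138) and Tet3 by −0.14 (adjusted p = 0.366). That list had a mean of −0.28, a median of 0.14 and no call (adjusted p = 0.908).

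**Figure D1:**
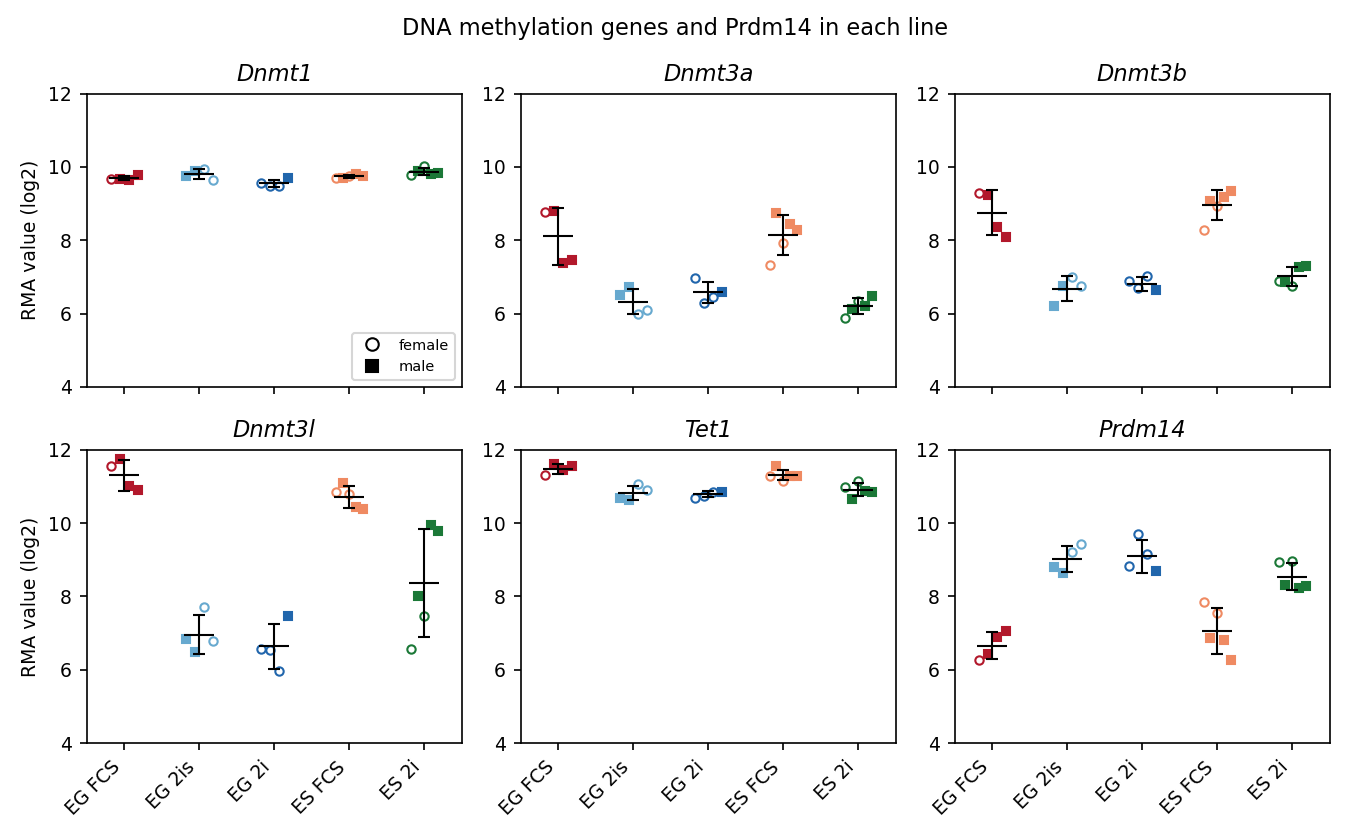
Log2 RMA level (vertical axis) of Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Tet1 and Prdm14 in each line of the 5 groups, with open circles for female and filled squares for male lines, and bars for the mean and SD. Dnmt3l stood at 10.71 ± 0.30 (SD, n = 5) in ES FCS lines and at 6.64 ± 0.62 (SD, n = 4) in EG 2i lines.

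Pluripotency genes split in the EG comparison. Prdm14, a repressor of FGF signalling and DNA methylation genes, rose by 2.17 (SE 0.24, 4.49-fold, adjusted p = 3.1e-06), Nanog rose by 0.73 (SE 0.17, adjusted p = 0.00430), and Tbx3, a T-box factor, rose by 1.35. Esrrb rose by 0.34 (adjusted p = 0.0481), which centring of the arrays ended (adjusted p = 0.0721), and which also ended without any 1 of EG FCS lines 1 and 2 or the 4 EG 2i lines (adjusted p = 0.0554 to 0.326). Pou5f1 differed by −0.16 (adjusted p = 0.0941), Sox2 by 0.06 (adjusted p = 0.636) and Klf4 by −0.09 (adjusted p = 0.786). Without EG FCS line 1 the adjusted p was 0.052 for Nanog and 0.0611 for Tbx3. Of 11 naive factors 4 rose and 1 fell (6 and 1 adjusted over the list alone), Klf2 being the one that fell, by 0.57, and the list as a whole was not called (adjusted p = 0.0759). Of 12 core pluripotency genes 1 rose and 4 fell (1 and 6 adjusted over the list alone). Lin28a, an RNA-binding protein that blocks let-7, fell by 3.37. Utf1, a chromatin protein, fell by 2.65, and Dppa4 fell by 1.19. The core list was lower (adjusted p = 0.00769, and adjusted p = 0.0471 with an estimated correlation), though after quantile normalization again its adjusted p was 0.0551. Among 9 primed epiblast genes 1 rose and 5 fell (1 and 5 adjusted over the list alone). Sox11 and Sox4 fell by 1.32 and 1.28, and Zic2 rose by 1.14. The primed list was lower with the preset correlation (adjusted p = 0.0184) and had an adjusted p = 0.361 with an estimated correlation. Without EG FCS line 1 or 2 it was not called (adjusted p = 0.0617 and 0.0502).

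Targets of ERK, the kinase downstream of the MEK that 2i inhibits, fell together. Of 20 ERK target genes 17 fell and 0 rose in EG lines (19 and 0 adjusted over the list alone), with a mean of −1.57 (adjusted p = 6.5e-19, and adjusted p = 3.3e-05 with an estimated correlation). Dusp6, a phosphatase of ERK, fell by 3.62 (SE 0.21, 12.3-fold, adjusted p = 1.6e-09), the immediate early gene Egr1 fell by 2.09 (SE 0.10, adjusted p = 3.4e-10), and the feedback inhibitor Spry4 fell by 2.90. The 3 that did not pass were Dusp1 at −0.86, Etv5 at 0.08 and Fosl1 at −0.26. The list stood at 7.96 ± 0.11 (SD, n = 4) in EG FCS lines and 6.40 ± 0.09 (SD, n = 4) in EG 2i lines. Of 14 Wnt targets 4 rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.290). Notum and Cdx1 rose by 1.59 and 1.13, and Bmp4, itself a signal, fell by 1.97. Of 9 BMP-SMAD targets 4 fell and 0 rose, the same numbers as adjusted over the list alone, among them Id1 by 1.06 and Id2 by 1.83 (adjusted p = 0.0349 for the list, 0.0503 when arrays were centred, 0.0545 and 0.0908 without EG FCS lines 3 and 4, and adjusted p = 0.227 with an estimated correlation). Of 10 LIF-STAT3 targets 1 rose and 5 fell (1 and 5 adjusted over the list alone), including Socs3 by 1.23, Pim3 by 0.98 and Junb by 0.97 (adjusted p = 0.00505 for the list, and adjusted p = 0.227 with an estimated correlation).

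Markers of the feeder layer were lower in EG 2i lines. Of 21 feeder fibroblast markers 12 fell and 0 rose (13 and 1 adjusted over the list alone), including Acta2, Thbs1 and Tagln (−2.31). The median of the list was −0.36, and Lum, Sparc, S100a4, Timp1 and Pdgfrb were not called. The list was at 6.52 ± 0.32 (SD, n = 4) in EG FCS, 5.6 ± 0.06 (SD, n = 4) in EG 2i and 5.58 ± 0.08 (SD, n = 4) in EG 2is lines (adjusted p = 3.4e-07 for EG 2i against FCS, and adjusted p = 0.229 with an estimated correlation). Of 13 primitive endoderm genes, some of them matrix genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone). Among these Lamb1, a laminin, fell by 2.80, Lrp2, an endocytic receptor, by 1.74 and Col4a1, a collagen, by 1.19 (adjusted p = 0.00133 for the list, and adjusted p = 0.227 with an estimated correlation). Of 11 trophoblast genes 2 fell and 0 rose (1 and 0 adjusted over the list alone), the keratins Krt18 by 2.19 and Krt8 by 1.48, and the list was not called (adjusted p = 0.665). The call of Krt8 ended without any 1 of EG FCS lines 1, 3 and 4 or the 4 EG 2i lines (adjusted p = 0.0532 to 0.141). With the feeder marker level as a term, Col4a1 (adjusted p = 0.285), Krt18 (adjusted p = 0.682), Pax6 (adjusted p = 0.565), Zic2 (adjusted p = 0.845), Notum (adjusted p = 0.257) and Bmp4 (adjusted p = 0.715) were no longer called. That level separated the cultures without overlap (6.13 to 6.91 in FCS lines, 5.44 to 5.71 in 2i and 2is lines). The term therefore takes up part of the culture effect itself. A call lost with it, here or in later comparisons, does not show that the RNA came from feeders.

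Germ cell and imprinted genes moved in both directions in EG lines. Of 18 methylation-dependent germline genes 3 rose and 5 fell (4 and 5 adjusted over the list alone), with Dazl up by 2.69 (SE 0.27, adjusted p = 1.2e-06) and Stk31 up by 1.10, while Mael, a piRNA pathway gene, fell by 1.91. The list was not called (adjusted p = 0.908). Of 10 primordial germ cell genes 4 rose and 3 fell (4 and 3 adjusted over the list alone). The receptor Kit rose by 1.96 and the alkaline phosphatase Alpl by 0.94, the regulator Prdm1 fell by 0.99, and the list was not called (adjusted p = 0.708). Of 23 imprinted genes 3 rose and 10 fell (3 and 11 adjusted over the list alone), with a list mean of −0.54 (adjusted p = 0.00505, and adjusted p = 0.0300 with an estimated correlation). Peg10 fell by 3.92 (SE 0.77, adjusted p = 8.9e-04), Peg3 by 1.88 and Nnat by 1.11, while Plagl1 rose by 1.5.

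Metabolic, cell cycle and control genes of EG lines were tested too. Of 13 glycolysis genes 1 rose and 6 fell (1 and 7 adjusted over the list alone). Pdk1, which restrains pyruvate dehydrogenase, fell by 2.80, the glucose transporter Slc2a1 by 0.97, and Pfkp rose by 1.45. The glycolysis list was lower (adjusted p = 0.00861, 0.0504 after quantile normalization again, and adjusted p = 0.397 with an estimated correlation). Of 14 proliferation genes 3 fell and 0 rose (4 and 0 adjusted over the list alone), among which Ccne1, cyclin E, fell by 1.27 (adjusted p = 0.00505 for the list, 0.0886 after quantile normalization again, and adjusted p = 0.227 with an estimated correlation). Of 16 cholesterol synthesis genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), and Msmo1 rose by 0.62 (adjusted p = 0.115 for the list). Of 12 Polycomb genes 3 rose and 4 fell (4 and 5 adjusted over the list alone), where Suz12 rose by 0.45 and Jarid2 fell by 0.67 (adjusted p = 0.775). Of 9 primitive streak genes 1 rose, Gsc by 1.24, and 0 fell (1 and 0 adjusted over the list alone). That list had a mean of 0.12, a median of −0.02 and no call (adjusted p = 0.71). Of 11 neural genes 2 fell, Map2 by 0.56 and Pax6 by 0.54, and 0 rose (2 and 0 adjusted over the list alone), with a list mean of −0.01, a median of 0.06 and adjusted p = 0.926. Of 3 two-cell-like genes 0 were called and 0 were called adjusted over the list alone (adjusted p = 0.486). Of 9 housekeeping genes 2 fell and 0 rose (4 and 0 adjusted over the list alone), among which Actb fell by 0.31 (adjusted p = 0.108 for the list). Further list members called were Stard4 (0.48), Mtf2 (0.40), Bambi (−0.48), Pcna (−0.40), Mki67 (−0.40) and Ywhaz (−0.23). The call of Mki67 ended without EG 2i line 4 (adjusted p = 0.0694). That of Ywhaz ended without EG FCS line 2 or 4 or EG 2i line 1 or 4 (adjusted p = 0.0653 to 0.104) and after quantile normalization again (adjusted p = 0.159). With the feeder marker level as a term Stard4, Bambi, Mki67 and Ywhaz were not called (adjusted p = 0.146 to 0.488). Of 2 X inactivation centre genes 1 fell and 0 rose, also adjusted over the list alone: Rlim fell by 0.83, and Xist differed by −0.28 (adjusted p = 0.455). That list had adjusted p = 0.179. Of 3 Y-linked genes 0 were called, also adjusted over the list alone (adjusted p = 0.798), and of 739 X-linked genes 91 rose and 68 fell (83 and 64 adjusted over the list alone, adjusted p = 0.519).

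**Figure D2:**
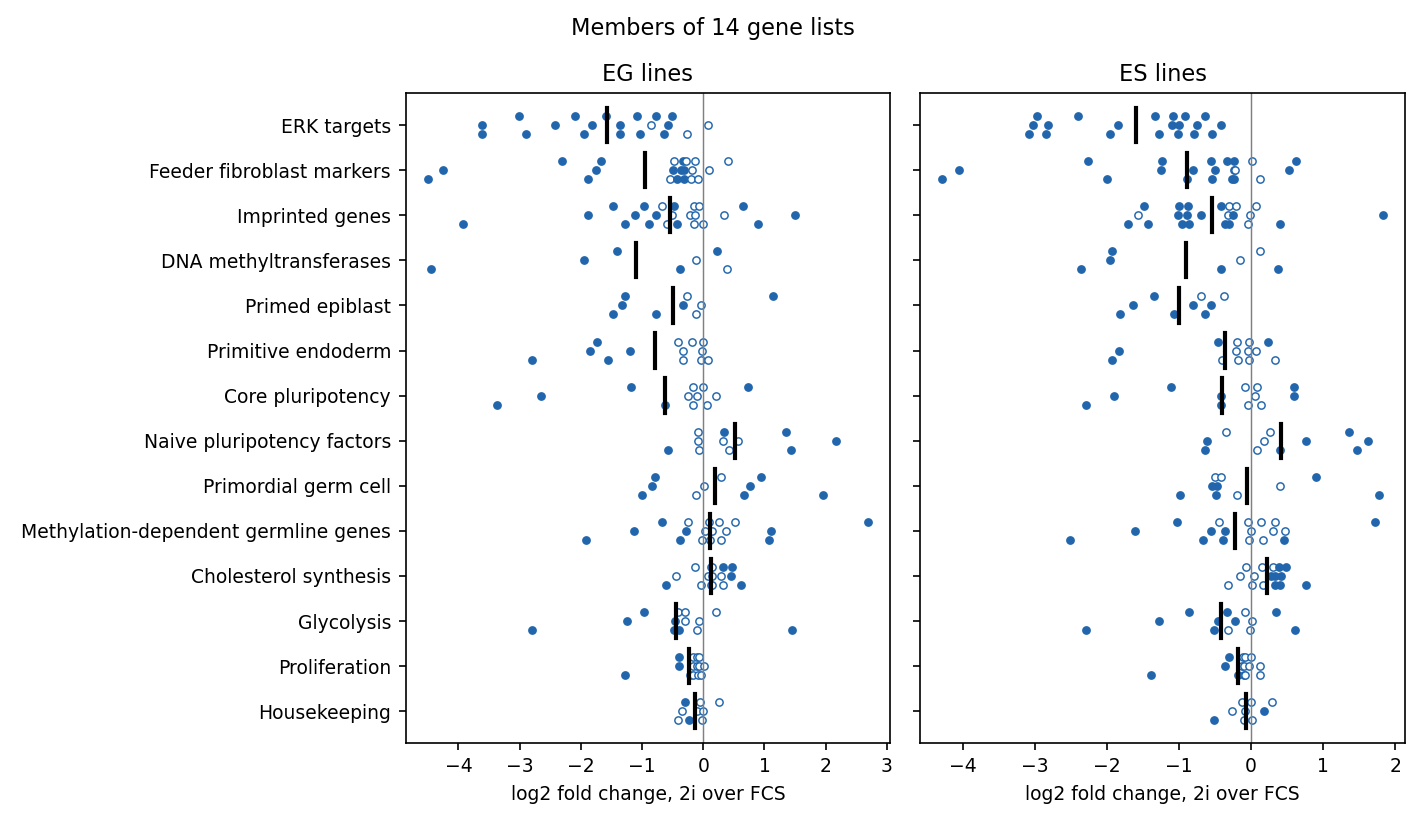
Log2 fold change of 2i over FCS (one axis) for the members of 14 gene lists (the other axis), in EG lines and ES lines, with filled points for genes of adjusted p under 0.05 and black bars for list means. The ERK targets have a mean of −1.57 in EG and −1.59 in ES lines.

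Lines moved to 2i after 48 hours in FCS were set against EG lines in FCS to ask whether a start in serum leaves the same profile. The same genes led: Acta2 fell by 4.52 (23-fold), Thbs1 by 4.37, Dnmt3l fell by 4.23 (18.8-fold) and Enpp3 fell by 4.07. Crxos rose by 3.65, Aqp3 by 3.21, Ppp1r14d by 3.03 and Bhmt by 2.93 (n = 4 and 4). Dazl rose by 2.30 (SE 0.26, 4.94-fold, adjusted p = 2.7e-06), Prdm14 by 2.23 and Nanog by 0.66, and Dnmt3a, Dnmt3b and Tet1 fell by 1.72, 2.07 and 0.67. Uhrf1 rose by 0.46 (adjusted p = 1.4e-04), and Dnmt1 differed by 0.13 (adjusted p = 0.215). Esrrb rose by 0.35 (adjusted p = 0.0321), a call that ended without any 1 of EG FCS lines 1 and 2 or EG 2is lines 1, 2 and 4 (adjusted p = 0.0633 to 0.213), and the adjusted p of Nanog was 0.0545 without EG FCS line 1. In total 5108 genes were called, 2542 higher and 2566 lower, 721 of them by at least 2-fold. Of these, 1785 higher and 1936 lower genes were shared with the EG 2i comparison, where 290 and 320 would be shared by independent lists, and 0 had opposite directions. Both comparisons use the same FCS lines, and the correlation of fold changes across genes, which are not independent replicates, was 0.932 against 0.517 simulated with no effect and 0.763 to 0.885 when the FCS lines were divided between them.

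Gene lists were tested in the 2is comparison as well. Of 20 ERK targets 18 fell and 0 rose (19 and 0 adjusted over the list alone), with a mean of −1.65 (adjusted p = 3.9e-19, and adjusted p = 3.1e-05 with an estimated correlation). Mki67 fell by 0.40 (adjusted p = 0.139 with the feeder marker level as a term), and the imprinted Igf2r rose by 1.12. Imprinted genes were lower, with 2 risen and 11 fallen of 23 (3 and 11 adjusted over the list alone; adjusted p = 0.00493, and adjusted p = 0.0307 with an estimated correlation). Of 16 cholesterol synthesis genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), with Msmo1 up by 0.84 and Fdft1 by 0.54 (adjusted p = 1.7e-04, and adjusted p = 0.421 with an estimated correlation). Feeder markers (14 of 21 fell, 16 adjusted over the list alone, adjusted p = 1.9e-07), primitive endoderm (8 of 13 fell, also adjusted over the list alone, adjusted p = 1.6e-04), primed epiblast (1 rose and 4 fell of 9, 1 and 5 adjusted over the list alone, adjusted p = 0.0102) and BMP-SMAD targets (4 of 9 fell, also adjusted over the list alone, adjusted p = 0.0376) were lower. With an estimated correlation the adjusted p of these lists was 0.323, 0.193, 0.421 and 0.323, and without EG FCS lines 3 and 4 that of the BMP-SMAD targets was 0.0597 and 0.108. Core pluripotency genes (1 rose and 4 fell of 12, 2 and 5 adjusted over the list alone) were lower, with adjusted p = 0.0211, 0.05 without EG FCS line 4, and adjusted p = 0.0926 with an estimated correlation. In the TET list (mean −0.38, median 0.04) and the trophoblast list (mean −0.26, median 0.03) mean and median differed in sign, as they did in the primordial germ cell list (mean 0.19, median −0.06), and none of these 3 was called.

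EG lines derived in 2i and EG lines moved to 2i were compared directly, and limma called 0 genes, while 2116 had an unadjusted p under 0.05 where chance gives 997. The lowest adjusted p was 0.137. The count was 5 with X dosage in place of sex, 1 with only the groups compared in the fit and 1 with the feeder marker level as a term. Cholesterol synthesis genes had a mean of −0.23 in 2i against 2is (adjusted p = 1.1e-05), glycolysis genes −0.18 (adjusted p = 0.0119) and germline genes 0.22 (adjusted p = 0.0152), with 0 members called in each, also adjusted over the list alone, and with adjusted p = 0.824 for each with an estimated correlation. Glycolysis was not called after quantile normalization again (adjusted p = 0.158) or without EG 2is line 1 or EG 2i line 1 (adjusted p = 0.225 and 0.131). The germline list was not called without EG 2is line 1 or 3 or EG 2i line 2 (adjusted p = 0.153, 0.363 and 0.348). Dnmt1 differed by −0.25 (adjusted p = 0.221) and Uhrf1 by −0.23 (adjusted p = 0.282). Adjusted over the list alone, 1 of 7 DNA methyltransferase genes was higher (Uhrf2, 0.42) and 2 were lower (Dnmt1 and Uhrf1). So adjusted, 1 gene was called in each of 4 other lists: Dppa3 (0.81, primordial germ cell), Zic1 (0.28, neural), Mtf2 (0.27, Polycomb) and Il6st (−0.35, LIF-STAT3).

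ES lines responded to 2i much as EG lines did. Crxos rose by 3.57 (SE 0.29, 11.9-fold, adjusted p = 2.6e-08, n = 5 and 5). The one-carbon enzyme Aldh1l1 rose by 3.00 (SE 0.19, 8.03-fold, adjusted p = 1.1e-09), Bhmt by 3.01 (8.06-fold), and Dmgdh, of choline breakdown, by 3.15. AA467197 rose by 3.42 and Cdo1, of cysteine breakdown, by 2.91 (7.50-fold). Thbs1 fell by 4.28 (19.4-fold) and Acta2 fell by 4.05 (16.6-fold). The epithelial splicing regulator Esrp1 fell by 3.92 (SE 0.15, 15.2-fold, adjusted p = 2.4e-12). The carbonic anhydrase Car4 fell by 3.87 (14.6-fold), Enpp3 fell by 3.51 (11.4-fold) and the amino acid transporter Slc7a7 fell by 3.11 (8.61-fold). In each of these genes every ES 2i line lay beyond every ES FCS line. In total 6298 genes were called, 3319 higher and 2979 lower, 768 of them by at least 2-fold. Within batch 1 (2 lines against 2) 2460 genes were called, and within batch 2 (3 against 3) 6114.

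Methylation and pluripotency genes that are named here and were called in both ES and EG lines changed in the same direction. Dnmt3a fell by 1.93 (SE 0.27, adjusted p = 1.8e-05), Dnmt3b by 1.95 (SE 0.22, adjusted p = 1.2e-06), Dnmt3l by 2.36 (SE 0.45, adjusted p = 4.0e-04) and Tet1 by 0.41 (adjusted p = 0.00308). Within batch 2 alone the adjusted p was 0.0882 for Dnmt3l and 0.0647 for Tet1. Uhrf1 rose by 0.38 (adjusted p = 2.0e-04), and Dnmt1 differed by 0.13 (adjusted p = 0.142), Tet2 by 0.44 (adjusted p = 0.155) and Tet3 by 0.06 (adjusted p = 0.650). Of 7 DNA methyltransferase genes 1 rose and 4 fell (1 and 4 adjusted over the list alone), with adjusted p = 0.104 for the list. Of 12 TET and demethylation genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Apobec1, a cytidine deaminase, up by 1.09, and with a mean of −0.12, a median of 0.03 and a test pointing up (adjusted p = 0.484). Gadd45a fell by 1.89. Prdm14 rose by 1.47 (SE 0.21, 2.77-fold, adjusted p = 1.8e-05), Nanog by 0.60 (adjusted p = 0.00360) and Tbx3 by 1.62. Esrrb differed by 0.27 (adjusted p = 0.0538), Klf4 by 0.18 (adjusted p = 0.456), Sox2 by −0.08 (adjusted p = 0.451) and Pou5f1 by −0.05 (adjusted p = 0.610). Of 12 core genes 2 rose and 5 fell (2 and 5 adjusted over the list alone, adjusted p = 0.107). Lin28a fell by 2.29 and Utf1 fell by 1.90. Of 11 naive factors 5 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.251).

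Among lineage lists, primed epiblast genes were lower in ES lines. Of 9 primed epiblast genes 7 fell and 0 rose (8 and 0 adjusted over the list alone): Fgf5 fell by 1.82, Sox11 by 1.63 and Sox4 by 1.35 (adjusted p = 4.5e-06 for the list, and adjusted p = 0.150 with an estimated correlation). Of 11 neural genes 3 fell and 0 rose, also adjusted over the list alone, Pax6 by 1.31, Nes by 0.84 and Map2 by 0.61 (adjusted p = 0.0682). Of 9 primitive streak genes 1 rose and 3 fell, also adjusted over the list alone, with Gsc up by 0.91 (adjusted p = 0.142). Of 13 primitive endoderm genes 1 rose and 3 fell, also adjusted over the list alone, Lamb1 by 1.93 and Lrp2 by 1.84 (adjusted p = 0.126), and of 11 trophoblast genes 1 rose and 3 fell, also adjusted over the list alone, Krt18 by 2.16 (adjusted p = 0.385). Of 18 germline genes 2 rose and 7 fell, also adjusted over the list alone, with Dazl up by 1.72 (SE 0.23, 3.29-fold, adjusted p = 1.2e-05) while Mael fell by 2.51 and Ddx4 by 1.61 (adjusted p = 0.142). Of 10 primordial germ cell genes 2 rose and 4 fell (3 and 6 adjusted over the list alone), and Kit rose by 1.78 while Prdm1 fell by 0.98 (adjusted p = 0.387). Feeder markers were at 6.46 ± 0.28 (SD, n = 5) in ES FCS and 5.57 ± 0.12 (SD, n = 5) in ES 2i lines, with 16 of 21 fallen and 2 risen, also adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.313 with an estimated correlation). With the feeder marker level as a term 4120 genes were called, 3468 of them among the 6298, and Col4a1 (adjusted p = 0.75), Krt18 (adjusted p = 0.552), Bmp4 (adjusted p = 0.133), Id3 (adjusted p = 0.591) and Map2 (adjusted p = 0.2) were not.

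Signalling and metabolic lists in ES lines gave the same directions as in EG lines where they were called. All 20 ERK targets fell, also adjusted over the list alone, with a mean of −1.59 (adjusted p = 6.6e-20, and adjusted p = 2.4e-05 with an estimated correlation), including Dusp6 by 3.08, Spry4 by 2.81, Egr1 by 2.39 and Myc by 3.03. The list stood at 7.84 ± 0.12 (SD, n = 5) in FCS and 6.25 ± 0.08 (SD, n = 5) in 2i. Of 23 imprinted genes 2 rose and 14 fell (2 and 15 adjusted over the list alone), Peg3 by 1.71 and Nnat by 1.49, with Plagl1 up by 1.83 (adjusted p = 1.3e-04, and adjusted p = 0.00356 with an estimated correlation). Of 9 BMP-SMAD targets 3 fell, also adjusted over the list alone, Id1 by 1.63 and Id3 by 1.38 (adjusted p = 0.0386, and adjusted p = 0.265 with an estimated correlation). Of 14 Wnt targets 5 rose and 3 fell (7 and 4 adjusted over the list alone), where Axin2 rose by 1.34 and Lef1 fell by 2.57, with a list mean of −0.06, a median of 0.22 and a test pointing up (adjusted p = 0.686). Of 10 LIF-STAT3 targets 2 rose and 3 fell (2 and 4 adjusted over the list alone, adjusted p = 0.135). Of 16 cholesterol genes 8 rose and 0 fell, also adjusted over the list alone, Msmo1 by 0.76 (adjusted p = 0.0269, and adjusted p = 0.575 with an estimated correlation). Of 13 glycolysis genes 2 rose and 7 fell, also adjusted over the list alone, and Pdk1 fell by 2.29 and Pfkl fell by 1.28 (adjusted p = 0.0386, 0.072 after quantile normalization again, and adjusted p = 0.553 with an estimated correlation). Of 14 proliferation genes 4 fell, also adjusted over the list alone, Ccne1 by 1.39 (adjusted p = 0.0471, 0.0854 after quantile normalization again, and adjusted p = 0.376 with an estimated correlation). Without 1 line these calls ended too: for BMP-SMAD targets without ES FCS line 1 or 3 or ES 2i line 2 (adjusted p = 0.0506 to 0.0987), and for cholesterol synthesis without ES FCS line 1 or ES 2i line 2 or 3 (adjusted p = 0.0592 to 0.101). For glycolysis they ended without ES FCS line 1 or 3 or ES 2i line 1 or 2 (adjusted p = 0.0506 to 0.113), and for proliferation without ES FCS line 1, 2 or 3 or ES 2i line 1, 2 or 5 (adjusted p = 0.0544 to 0.0900). With a replicate block for ES lines alone proliferation was not called either (adjusted p = 0.0572).

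Further list members called in ES lines were Plet1 (0.71), Xrcc1 (0.60), Il6st (0.36), Stard4 (0.34), Sdha (0.19), Mov10l1 (−1.02), Dlk1 (−1.02), Fgf8 (−0.65), Mki67 (−0.36), Wnt3 (−0.35), Bub1 (−0.31) and Hand1 (−0.27). The call of Hand1 ended without ES FCS line 3 (adjusted p = 0.0702), that of Plet1 with ES lines 4 and 5 averaged (adjusted p = 0.0831), and that of Sdha without any 1 of 8 lines, all but ES FCS line 1 and ES 2i line 4 (adjusted p = 0.0581 to 0.109). With the feeder marker level as a term Fgf8, Wnt3, Hand1, Stard4, Mki67, Bub1 and Sdha were not called (adjusted p = 0.0534 to 0.634).

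The lists left in the ES comparison were not called. Of 12 Polycomb genes 1 rose and 1 fell, also adjusted over the list alone, and Jarid2 was the one that fell, by 0.68 (adjusted p = 0.650). Of 3 two-cell-like genes 0 were called, also adjusted over the list alone (adjusted p = 0.304). Of 9 housekeeping genes 1 rose and 1 fell (0 and 1 adjusted over the list alone), and Pgk1 fell by 0.51 (adjusted p = 0.440). Rlim fell by 0.66 and Xist differed by −0.53 (adjusted p = 0.0553, and 0.0259 with a replicate block for ES lines alone), with 2 of 2 X inactivation centre genes fallen adjusted over the list alone and adjusted p = 0.142 for the list. Of 3 Y-linked genes 0 were called (adjusted p = 0.506), and of 739 X-linked genes 75 rose and 106 fell (72 and 101 adjusted over the list alone, adjusted p = 0.484).

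The EG and ES responses, which share no array, were then set against each other. Across all 19938 genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.80 and Spearman's rho = 0.639, and the slope of ES on EG was 0.844. For the 3276 genes called in both, r was 0.942 and 99.2% had the same sign. Of the genes higher in 2i, 1613 were called in both where independent lists would share 379, and of the lower ones 1638 where they would share 372, while 8 and 17 were called in opposite directions.

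**Figure D3:**
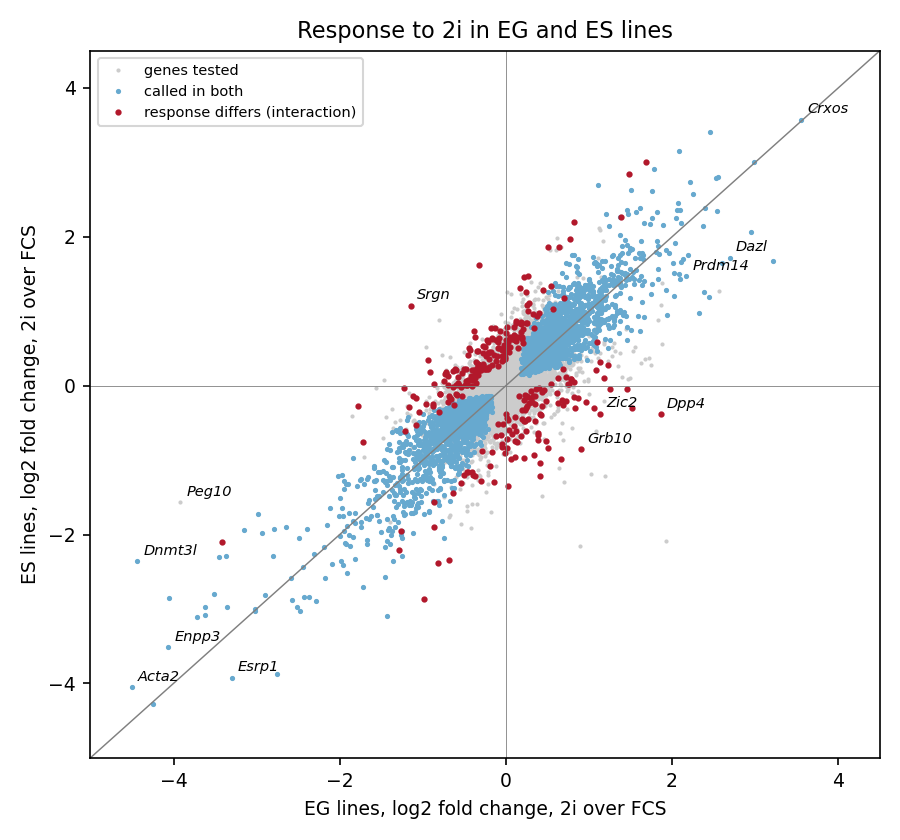
Log2 fold change of 2i over FCS in EG lines (horizontal axis) and ES lines (vertical axis), 1 point per gene, with grey for all genes tested, blue for the 3276 called in both and red for the 287 whose responses differed by the interaction test. The straight line marks equal change.

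A test of the difference between the responses (the interaction of culture and cell type) called 287 genes, 113 with the larger value in EG and 174 with the larger value in ES lines. Dpp4, a cell surface peptidase, had the largest difference, 2.25 on the log2 scale (SE 0.38, adjusted p = 0.00826), with a rise of 1.86 in EG lines and −0.39 in ES lines. Grb10, an imprinted adaptor of insulin receptor signalling, rose by 0.90 in EG lines and fell by 0.85 in ES lines (difference 1.76, SE 0.41, adjusted p = 0.0408), and Srgn, a proteoglycan of secretory granules, fell by 1.15 in EG and rose by 1.08 in ES lines (difference −2.22, SE 0.46, adjusted p = 0.0200). Apela, a peptide hormone gene, fell by 1.78 in EG lines and differed by −0.27 in ES lines, and Sfrp1, a Wnt antagonist, rose by 0.82 and 2.20. Fndc3c1 fell in both, to means below the background level (difference 1.88), Adgre5 rose in EG lines by 1.52 (difference 1.81), and Susd2 rose in ES lines by 1.62 (difference −1.95). Apobec1 had a difference of −0.83 (adjusted p = 0.00939), Zic2 of 1.51, Nes of 1.34 and Pax6 of 0.77. Without ES FCS line 5 the calls of Srgn, Sfrp1, Zic2, Fndc3c1, Adgre5, Grb10, Susd2 and Pax6 ended (adjusted p = 0.0524 to 0.0900). For all of these but Sfrp1 other single lines did so too. Dpp4, Apela, Apobec1 and Nes were called with any 1 line left out. Dnmt3l (−2.08, adjusted p = 0.131), Dazl (0.97, adjusted p = 0.18) and Prdm14 (0.70, adjusted p = 0.291) were not called.

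Among lists, the interaction test gave larger values in EG lines for primed epiblast (adjusted p = 0.00440), streak (adjusted p = 0.0222), neural (adjusted p = 0.0222), germline (adjusted p = 0.0101) and two-cell-like genes (adjusted p = 0.0399), and smaller ones for primitive endoderm (adjusted p = 0.0302). With an estimated correlation the adjusted p was 0.330 for the first 3 and 0.455 for the others. Members called were 1 of 9 primed epiblast genes (4 adjusted over the list alone) and 2 of 11 neural genes (3 adjusted over the list alone), and 0 in the other 4 lists, where 1 streak gene and 4 endoderm genes were called adjusted over the list alone. After quantile normalization again the neural list was not called (adjusted p = 0.0837), and leaving out EG 2i line 4 ended it too (adjusted p = 0.0632). Single lines also ended the calls of the streak (adjusted p = 0.0682 without ES 2i line 3) and germline lists (adjusted p = 0.0532 without EG 2i line 2) and the endoderm list (adjusted p = 0.0508 to 0.103 without EG FCS line 1 or 4 or EG 2i line 4). The two-cell-like list lost its call as well (adjusted p = 0.0508 to 0.0954 without EG FCS line 1 or 2, EG 2i line 1 or 2, ES FCS line 2 or ES 2i line 1, 3 or 5). The count of 287 depended on single lines: it was 157, 158 and 155 without EG FCS lines 1, 3 and 4, 123 without EG 2i line 3, 110 and 112 without ES FCS lines 4 and 5, and 180 and 178 without ES 2i lines 4 and 5. ES FCS lines 4 and 5 were the most alike of all pairs within a group (correlation 0.998, 1 gene at least 2-fold apart), and whether ES lines 4 and 5 are separate lines is not known. If they are not, n = 5 for ES lines is too high. With ES lines 4 and 5 averaged in each culture the count was 62, and without the 3 female lines of low X dosage 138. With ES samples of the same number taken as 1 line (a replicate block for ES lines alone) it was 178, and Fndc3c1, Susd2 and Pax6 were not called (adjusted p = 0.0690 to 0.0844). The count was 179 with array run in place of batch, 438 with neither batch nor sex term and 488 with X dosage in place of sex. With arrays centred on their medians it was 469, 98 larger in EG and 371 larger in ES lines.

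The question of how EG and ES cells differ in the same culture gave few genes in FCS. Nod1, a sensor of bacterial peptidoglycan, was at 4.38 ± 0.19 (SD, n = 4) in EG FCS lines, below the background level of 4.88, and at 5.84 ± 0.61 (SD, n = 5) in ES FCS lines. The fitted difference of −2.15 (SE 0.19, adjusted p = 1.1e-05) includes the batch term, for which Nod1 was the 1 gene called, and without that term it was −1.43 (adjusted p = 0.160). Gbp2b, an interferon-induced GTPase, was lower in EG FCS lines by a difference of −0.81 (SE 0.11, 1.76-fold, adjusted p = 0.00370). These were the 2 genes called, with 979 at an unadjusted p under 0.05. Without EG FCS line 1 the count was 4, and without ES FCS line 2 Gbp2b was not called (adjusted p = 0.0578). The count was 6 without the batch term, 5 without the 3 female lines of low X dosage and 1 with only the groups compared in the fit. Lists that differed without a single called member were primitive endoderm (mean 0.36, adjusted p = 3.4e-05), streak (−0.20, adjusted p = 2.5e-04), cholesterol synthesis (−0.16, adjusted p = 2.5e-04), primordial germ cell (−0.25, adjusted p = 0.00145) and primed epiblast genes (−0.21, adjusted p = 0.0162). Adjusted over the list alone, 1 endoderm gene was higher, 1 streak gene was lower and 0 were called in the other 3. With an estimated correlation the adjusted p was 0.209, 0.209, 0.593, 0.266 and 0.593. The germ cell list was not called without EG FCS line 2 (adjusted p = 0.087), nor the primed list without EG FCS line 3 or 4 or ES FCS line 2 (adjusted p = 0.225, 0.224 and 0.435).

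In 2i, EG lines differed from ES lines at 742 genes, 240 higher and 502 lower in EG lines, 39 of them by at least 2-fold. At an unadjusted p under 0.05 there were 3742. Nod1 was at 4.5 ± 0.17 (SD, n = 4) in EG 2i lines, again below the background level, and at 6.24 ± 0.81 (SD, n = 5) in ES 2i lines. Its fitted difference was −2.47 (SE 0.19, adjusted p = 1.1e-06), and −1.79 without the batch term (adjusted p = 0.00256). Susd2 was lower in EG 2i lines by a difference of −2.07 (SE 0.37, 4.19-fold, adjusted p = 0.00600, n = 4 and 5), the actin-binding Cnn2 by −1.44 and Aldh1l1 by −1.37 (SE 0.23, 2.59-fold, adjusted p = 0.00428). Dpp4 was higher by 1.84 (SE 0.30, 3.58-fold, adjusted p = 0.00373), the amino acid transporter Slc43a1 by 1.48 (SE 0.18, 2.78-fold, adjusted p = 3.6e-04), Porcn, which acylates Wnt proteins, by 1.48 and the histidine-degrading Hal by 1.45. Among list members Zic2 (1.09), Nes (0.88), Tubb3 (0.87), Ndn (0.76), Dusp5 (0.53) and Ccne1 (0.34, adjusted p = 0.0418) were higher in EG 2i lines, and Lamb1 (−0.90), Apobec1 (−0.62), Cish (−0.39) and Fdft1 (−0.36) were lower. Without ES 2i line 1 the calls of Hal and of each of these list members but Apobec1 ended (adjusted p = 0.0506 for Nes to 0.153 for Dusp5), and for all but Hal and Tubb3 other single lines ended them too. Ccne1 was not called without EG 2i line 1, 3 or 4 or ES 2i line 1, 2, 4 or 5 (adjusted p = 0.0548 to 0.123), without the batch term (adjusted p = 0.0898) or with centred arrays (adjusted p = 0.0726). Dazl (0.93, adjusted p = 0.0792) and Dnmt3l (−1.20, adjusted p = 0.247) were not called. Cholesterol synthesis genes had a mean of −0.26, with 1 of 16 fallen (3 adjusted over the list alone). That list had adjusted p = 0.00132, and adjusted p = 0.541 with an estimated correlation. The count of 742 was 301 without EG 2i line 3, 339 without ES 2i line 1, 460 without ES 2i line 2, and 201 with batch 1 arrays alone, of which 171 were among the 742. With only the groups compared in the fit it was 15, and without the batch term 1758. It was 308 without the 3 female lines of low X dosage, 414 with ES lines 4 and 5 averaged and 1957 with neither batch nor sex term. With arrays centred on their medians 166 genes were higher and 844 lower.

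EG lines moved to 2i differed from ES 2i lines at 9 genes, all lower in EG lines, with 1872 at an unadjusted p under 0.05. Nod1 was at 4.56 ± 0.24 (SD, n = 4) in EG 2is lines, below the background level, with a fitted difference of −2.39 (SE 0.19, adjusted p = 1.6e-06), and −1.69 without the batch term (adjusted p = 0.0382). Apobec1 was lower by a difference of −0.76 (adjusted p = 0.0141, n = 4 and 5), Ggct, of glutathione metabolism, by −0.73, Capsl by −0.70 and Fanci, of DNA crosslink repair, by −0.66 (adjusted p = 0.0254, and 0.0585 after quantile normalization again). The calls of Apobec1, Ggct, Capsl and Fanci ended without EG 2is line 2 (adjusted p = 0.0958 to 0.128) or ES 2i line 2 (adjusted p = 0.105 to 0.208). Those of the last 3 ended without EG 2is line 4 (adjusted p = 0.0838 to 0.0988), with Capsl also not called without ES 2i line 1 (adjusted p = 0.0541). The X-linked list was higher (mean 0.08, adjusted p = 0.00406, and adjusted p = 0.813 with an estimated correlation), with 0 members called, also adjusted over the list alone. Single lines moved this count: it was 17, 2, 14 and 3 without EG 2is lines 1, 2, 3 and 4, and 1 and 43 without ES 2i lines 2 and 3. It was 33 without the batch term, 4 without the sex term and 0 with neither, 0 with only the groups compared, 3 with ES lines 4 and 5 averaged and 18 with X dosage in place of sex.

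Sex was compared within each culture. In 2i and 2is lines (7 female, 6 male) female lines had the higher level at 609 genes and the lower level at 422, 1031 in all, and of 242 X-linked genes called 241 were higher and 1 lower. The X-linked genes Nxf3, an RNA export factor, and Armcx1 were higher by 2.18 (SE 0.27, 4.52-fold, adjusted p = 3.2e-04) and 1.90 (SE 0.20, 3.74-fold), and the antigen-presenting H2-Eb1 was higher by 1.89 (3.69-fold). The Y-linked Eif2s3y, a translation factor, was lower by a difference of −3.56 (SE 0.15, adjusted p = 9.1e-11) and Uty, a histone demethylase homologue, by −2.89. Female levels of both are background, which limits the size of these differences, also in FCS. Dazl was higher in female lines by 0.85 (SE 0.21, 1.80-fold, adjusted p = 0.0265), as were Gadd45a by 1.17, Zdbf2 by 1.11, Hormad1 by 0.96 and Sox2 by 0.26, and the keratin gene Krt7 (−0.66) was lower. Others named by the rule were Usp26 (1.73), Timp1 (0.68), Taf7l (0.66), Hprt (0.54) and Nsdhl (0.49), higher in female lines, and Uba1y (−1.30), Khdc3 (−1.26), Spred1 (−0.68), Ifitm1 (−0.59), Eomes (−0.51), Tpi1 (−0.49), Dkk1 (−0.39) and Mcm6 (−0.19), lower. Without EG 2i line 4 the calls of Usp26, Taf7l, Khdc3, Ifitm1, Eomes, Tpi1 and Mcm6 ended (adjusted p = 0.052 to 0.182), and for all of these but Taf7l and Tpi1 other single lines ended them too. Spred1 was not called without ES 2i line 3 (adjusted p = 0.0643), nor Eomes and Mcm6 with centred arrays (adjusted p = 0.0584 and 0.0843). Prdm14 (0.59, adjusted p = 0.0830) and Xist (0.04, adjusted p = 0.932) were not called. The X-linked list was higher (241 risen and 1 fallen of 739, 318 and 10 adjusted over the list alone; adjusted p = 1.4e-24, and adjusted p = 0.0556 with an estimated correlation). Y-linked genes were lower (2 of 3, also adjusted over the list alone; adjusted p = 2.5e-07, and adjusted p = 0.0115 with an estimated correlation), and so were glycolysis genes (4 of 13, 6 adjusted over the list alone; adjusted p = 5.0e-04, and adjusted p = 0.567 with an estimated correlation). The count of 1031 was 586 without EG 2is line 1, 603 without EG 2is line 4, 593 without EG 2i line 4 and 1804 without EG 2i line 1. It was 484 with only the groups compared and 656 with ES lines 4 and 5 averaged. The call of Dazl ended without EG 2is line 1 (adjusted p = 0.0754), EG 2is line 4 (adjusted p = 0.0781), ES 2i line 2 (adjusted p = 0.0526), ES 2i line 3 (adjusted p = 0.0694) or ES 2i line 5 (adjusted p = 0.0513). With arrays centred on their medians 763 genes were higher and 301 lower.

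In FCS (3 female and 6 male lines) 5 genes were called, with 1054 at an unadjusted p under 0.05. Efhc2, an X-linked gene, was higher in female lines by 1.84 (SE 0.29, 3.58-fold, adjusted p = 0.0351), and Eif2s3y and Uty were lower by differences of −3.54 and −2.37. The other two, 3830417A13Rik (0.83) and 4930519F16Rik (1.12), were named after their values were seen. The count was 11 without EG FCS line 1, 3 without ES FCS line 1, and 2 without EG FCS line 4 or any 1 of ES FCS lines 2, 3, 4 and 5. The call of Efhc2 ended in 6 of these cases (adjusted p = 0.290, 0.0543, 0.214, 0.594, 0.145 and 0.154 without ES FCS line 1, EG FCS line 4 and ES FCS lines 2, 3, 4 and 5). Several lists were higher in female lines: X-linked genes (3 of 739, 6 adjusted over the list alone, adjusted p = 1.7e-14), feeder markers (0 members called, also adjusted over the list alone, adjusted p = 1.7e-07), imprinted genes (0, also adjusted over the list alone, adjusted p = 0.00123) and the X inactivation centre (0, and 1 adjusted over the list alone, adjusted p = 0.0188). With an estimated correlation the adjusted p was 0.134, 0.396, 0.0134 and 0.0962 for these 4 lists, and the X inactivation centre was not called without ES FCS line 3 (adjusted p = 0.376). Y-linked genes were lower (2 of 3, also adjusted over the list alone; adjusted p = 5.8e-14, and adjusted p = 4.5e-04 with an estimated correlation).

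The test of whether the sex difference changed with culture called 0 genes in limma (1250 at an unadjusted p under 0.05, lowest adjusted p 0.468), and 2 without EG 2i line 1. X-linked genes had the larger female excess in 2i (mean 0.14, adjusted p = 3.1e-06), and feeder markers (−0.26, adjusted p = 2.9e-04), glycolysis (−0.26, adjusted p = 6.5e-04) and trophoblast genes (−0.42, adjusted p = 0.00379) the smaller, with 0 members called over all genes. Adjusted over the list alone, 3 trophoblast genes were called and 0 in the other 3 lists, and with an estimated correlation the adjusted p was 0.540 for each. The X dosage of a line was 0.50 ± 0.28 (SD, n = 7) in female and −0.14 ± 0.08 (SD, n = 6) in male 2i lines (exact permutation p = 0.00117). In FCS lines it was 0.24 ± 0.11 (SD, n = 3) and −0.06 ± 0.02 (SD, n = 6), with an exact permutation p = 0.0119, the smallest possible. Between female lines of the 2 cultures no difference beyond chance was found (exact permutation p = 0.167), which does not show that they are equal. Among female 2i lines EG 2i line 1 was at −0.04, just above the highest male 2i line, and EG 2i lines 2 and 3 were at 0.68 and 0.72. Female 2i lines other than EG 2i line 1 ran from 0.27 to 0.72, and female FCS lines from 0.12 to 0.35. The test was not repeated without EG 2i line 1.

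**Figure D4:**
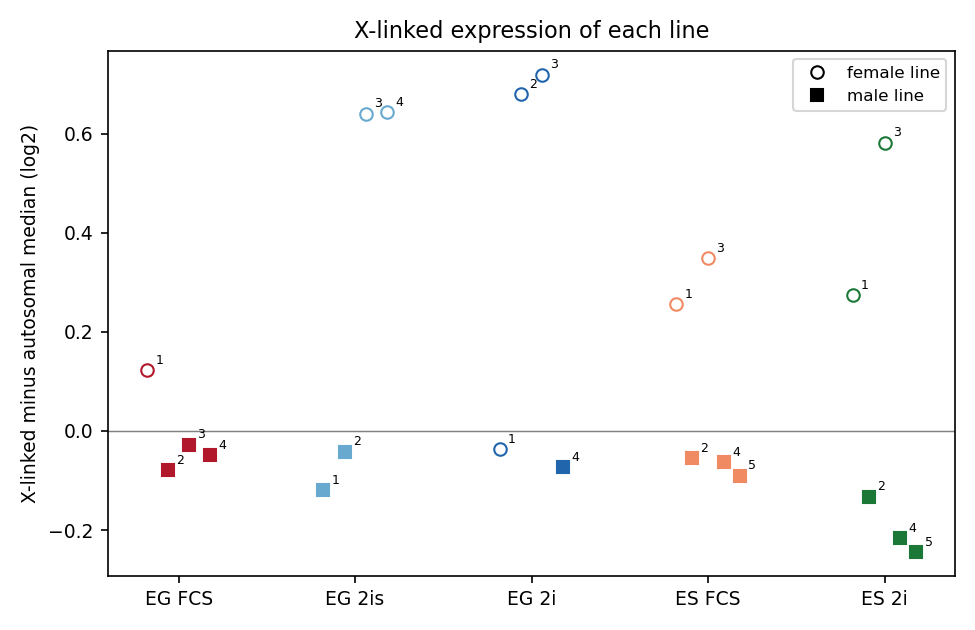
X dosage of each line, the median log2 level of X-linked genes minus that of autosomal genes (vertical axis), by culture and sex, with replicate numbers beside the points. Female lines in 2i run from −0.04 to 0.72, and male lines in 2i from −0.24 to −0.04.

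The spread between lines of a culture was measured to ask whether lines in 2i are more alike. It was 0.152 ± 0.024 (SD, n = 9) in FCS and 0.168 ± 0.029 (SD, n = 13) in 2i lines on the log2 scale (exact permutation p = 0.184), a difference not beyond chance. Without batch and sex terms the difference was −0.034 (exact permutation p = 0.00417), without the sex term alone −0.037 (exact permutation p = 0.00396) and without the batch term alone −0.013 (exact permutation p = 0.288). With batch 1 arrays alone the values were 0.168 and 0.162 (exact permutation p = 0.671).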

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

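Chosen only after the results were seen were the tests of Eif2s3y and of escape genes, the 3 tests of the EG 2i against ES 2i count, the test of contractile against collagen markers and the replicate block for ES lines alone. All regroupings, the test along the X chromosome and the ERK test were planned.

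A few single lines stood apart from their group by a gap test. Tet3 was at 6.11 in EG 2is line 1, with the others at 5.83 to 5.86, and at 6.06 in ES FCS line 3, with the others at 5.78 to 5.82. ES FCS line 3, a female line, also had Pou5f1 at 11.69, with the others at 11.59 to 11.61, and Xist at 6.34, with the others at 4.73 to 5.05. Of 90 groups of values tested chance gives 4.5 such gaps, and 4 were seen.

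The EG and ES responses to 2i differed at 287 genes by the interaction test. Those named are Dpp4 (2.25), Fndc3c1 (1.88), Adgre5 (1.81), Grb10 (1.76), Zic2 (1.51), Nes (1.34), Pax6 (0.77), Srgn (−2.22), Susd2 (−1.95), Apela (−1.52), Sfrp1 (−1.38) and Apobec1 (−0.83), each the EG minus the ES log2 fold change. Fndc3c1 was below the background level in 2i lines of both kinds, so its value rests on the FCS levels and the background. Of 100 assignments of cell type within each culture, the real one included, 2 gave at least as many genes. The highest other gave 432. Such a count was uncommon among the assignments if the ES samples are separate lines, but chance is not excluded. With ES samples of the same number taken as 1 line the count was 178 (a replicate block for ES lines alone).

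Probe sets without a single gene, 7064 in number, also changed with culture: 844 were called in EG 2i against FCS (353 higher, 491 lower), 737 in EG 2is against FCS (357 and 380) and 922 in ES 2i against FCS (426 and 496).

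EG 2i line 1, a female line, had X-linked genes near the level of male lines. Its Eif2s3y level of 4.61, beside 4.74 ± 0.08 (SD, n = 9) in the other female lines and 7.55 in the lowest male line, argues against a wrong sex label or male cells in the sample. Genes that escape X inactivation were lower than in EG 2i lines 2 and 3 by a median difference of −0.75 (7 genes), beside −0.69 for 262 other X-linked genes, which argues against silencing of 1 X chromosome that spares escape genes. In each of 4 equal parts of the gene order along X, at least 91.2% of genes lay below both other female lines (autosomal genes 44.3%). As a hypothesis, the loss of 1 X chromosome along its whole length could account for this, and DNA was not analysed here.

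More genes differed between EG 2i and ES 2i lines (742) than between EG 2is and ES 2i lines (9). With X dosage as a term the first count was 868, and without the 3 female lines of low X dosage, so with fewer lines, the counts were 308 and 12, which argues against X dosage as the whole cause. The lowest count with 1 line left out was 301, above the highest of 43 for EG 2is, which argues against 1 line as the cause, though with only the groups compared in the fit the counts were 15 and 0. A difference between EG 2i and EG 2is lines themselves cannot be told apart from noise: 2116 genes had an unadjusted p under 0.05, and limma called 0, or 5 with X dosage in place of sex, 1 with only the groups compared and 1 with the feeder marker level as a term. Whether the way the EG lines were derived plays a part stays open.

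Feeder fibroblast markers and ERK targets were both lower in 2i. Across the 9 FCS lines contractile markers followed collagen markers (r = 0.968, exact permutation p = 2.5e-05, adjusted p = 5.0e-05 over 2 relations; rho = 0.95, exact permutation p = 3.5e-04; r = 0.924 without the 2 farthest lines, exact permutation p = 0.00238). As a hypothesis, RNA of fibroblast-like cells in the FCS arrays could give part of the fall of contractile markers, since the slope gives −1.63 ± 0.16 (SE) where −3.15 was seen, but expression of both by the cells themselves in serum would give the relation too, and feeders and medium changed together. ERK targets differed by 0.15 per log2 unit of collagen markers (r = 0.603, exact permutation p = 0.0843; rho = 0.533, exact permutation p = 0.148; r = −0.095 without the 2 farthest lines, exact permutation p = 0.847). That slope gives a fall of −0.22 ± 0.11 (SE), where −1.58 was seen. Both slopes were carried below the collagen levels of the FCS lines (6.18 to 7.51), to 5.27 in 2i lines. If the relation stays linear there, the ERK values argue against such RNA as the whole cause of the lower ERK targets.

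For the other comparisons the arrays were regrouped. EG 2i against FCS (4764 genes) and EG 2is against FCS (5108) were each matched by 1 of 35 splits, the real one, with highest others of 526 and 5, and ES 2i against FCS (6298) by 1 of 100, with a highest other of 2398, so chance can be excluded. The same holds for female against male in 2i (1031 genes, 1 of 100 splits, highest other 527). Where ES lines take part, this rests on the ES samples being separate lines. EG 2is against ES 2i (9 genes) was matched by 2 of 100 splits, with a highest other of 115. There another split called far more genes, so chance is not excluded. Chance cannot be excluded for EG FCS against ES FCS (2; 9 of 100, highest other 395) or female against male in FCS (5; 6 of 84, highest other 469). In these and in EG 2is against ES 2i some splits called several times the real count, for reasons not tested. The EG splits that follow array run called 0 genes. For EG 2i against 2is (0 genes; 35 of 35 splits, highest other 532) and the interaction of sex and culture (0 genes; 100 of 100, highest other 123) every split calls at least as many, so regrouping decides nothing.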

How the results depend on the processing

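Alternatives with X dosage in place of sex, without the 3 female lines of low X dosage, with ES lines 4 and 5 averaged, within single array runs, with batch 1 alone for EG against ES, with the feeder marker level as a term, with a replicate block for ES lines alone and without the batch or sex term for the spread were chosen only after the results were seen. The setting without the 3 lines was first run for the female against male comparisons too and then withdrawn there, because it picks lines by the levels compared. Where the construction of an alternative does not show it (fewer arrays, more or fewer genes, a fold minimum), the cause was not tested.

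A 2-fold minimum gave 631 genes for EG 2i against FCS, 721 for EG 2is against FCS, 768 for ES 2i against FCS, 1 for EG FCS against ES FCS, 39 for EG 2i against ES 2i, 1 for EG 2is against ES 2i, 48 for the interaction of culture and cell type and 55 for female against male in 2i. Without the batch term there were 6 genes for EG FCS against ES FCS, 1758 for EG 2i against ES 2i and 33 for EG 2is against ES 2i. Without the sex term there were 4 for EG 2is against ES 2i. With neither term there were 4, 1957 and 0 genes for these 3 comparisons and 438 for the interaction, and the difference in spread was −0.034, or −0.037 without the sex term alone and −0.013 without the batch term alone. With array run in place of batch there were 179 for the interaction and 2 for female against male in FCS.

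With only the groups compared in the fit there was 1 gene for EG 2i against 2is, 1 for EG FCS against ES FCS, 15 for EG 2i against ES 2i, 0 for EG 2is against ES 2i, 484 for female against male in 2i and 2 in FCS. For EG 2i against ES 2i the median residual SD was 0.124 with 5 degrees of freedom, against 0.129 with 15 in the fit of all arrays. Centred arrays gave 469 genes for the interaction. The filter at the 40th percentile gave 0 for EG FCS against ES FCS, and every probe set tested on its own gave 14 for female against male in FCS and 1 for the interaction of sex and culture. Male lines alone gave 2282 and female lines alone 1690 for EG 2i against FCS, where a single line of 1 group is assumed to vary like the others. ES lines of batch 1 alone gave 2460. The rank correlation of the EG and ES responses was 0.639.

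Whether the numbers of the lines pair them across cultures stays open. Same-numbered ES lines match in sex in 5 of 5 pairs, but the values do not show a pairing: the deviation of a line from its group correlated with that of the line of the same number at −0.01 to 0.24 in ES lines, where 1 of 5 was the best match, and at −0.13 to 0.07 for EG FCS and EG 2i, −0.12 to 0.05 for EG FCS and EG 2is and −0.56 to 0.32 for EG 2is and EG 2i. A replicate block, fitted with only the groups compared and in place of batch, uses up degrees of freedom and also pairs EG lines by number. It gave 1929 genes for EG 2i against FCS, 0 for EG FCS against ES FCS, 0 for EG 2i against ES 2i, 0 for EG 2is against ES 2i and 5 for the interaction. The same block gave 5278 for EG 2is against FCS and 5900 for ES 2i against FCS. A replicate block for ES lines alone, with all arrays in the fit, gave 178 for the interaction and 6176 for ES 2i against FCS.

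Of the later alternatives, X dosage in place of sex gave 5 genes for EG 2i against 2is, 18 for EG 2is against ES 2i and 488 for the interaction. Without the 3 female lines of low X dosage there were 5 for EG FCS against ES FCS, 308 for EG 2i against ES 2i and 138 for the interaction. With ES lines 4 and 5 averaged there were 414 for EG 2i against ES 2i, 3 for EG 2is against ES 2i, 62 for the interaction, 656 for female against male in 2i and 2 in FCS. With the feeder marker level as a term there was 1 for EG 2i against 2is, 4120 for ES 2i against FCS, 4 for EG FCS against ES FCS and 2 for female against male in FCS. Array run 1 alone gave 1 gene for EG 2i against FCS, where the FCS lines are male and the 2i lines female, and 363 for EG 2is against FCS, and array run 2 alone gave 1602 and 1759. Batch 1 arrays alone gave 201 for EG 2i against ES 2i.

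With each line left out in turn the counts ran from 3441 to 4663 for EG 2i against FCS, 3973 to 5059 for EG 2is against FCS, 0 to 0 for EG 2i against 2is, 5546 to 6163 for ES 2i against FCS, 2 to 4 for EG FCS against ES FCS, 301 to 872 for EG 2i against ES 2i, 1 to 43 for EG 2is against ES 2i, 110 to 390 for the interaction of culture and cell type, 586 to 1804 for female against male in 2i, 2 to 11 in FCS and 0 to 2 for the interaction of sex and culture. The correlation of responses ran from 0.774 to 0.810, the difference in spread from −0.022 to −0.0067, and the X-linked excess of female lines from 0.52 to 0.63 in 2i and 0.22 to 0.38 in FCS.

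Of 7462 alternative values for 274 called results of single genes, 6736 kept direction and call, 726 lost the call and 0 reversed. Of 1333 for 50 called lists, 1162 kept both, 171 lost the call and 0 reversed. Among results not called, 67 of 4478 values for genes and 130 of 4767 for lists passed the threshold. The calls of the ERK and imprinted lists changed under no alternative run in EG 2i against FCS or ES 2i against FCS. Signal over background limits the dim genes, since 23.7% of genes lay below the highest female level of Eif2s3y.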

Other observations

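No hypothesis was tested in this part, and the values below were picked out only after the results were seen. Some lines of a group differed widely in single genes. Dnmt3l was at 6.57, 8.0 and 7.47 in ES 2i lines 1, 2 and 3 and at 9.95 and 9.79 in lines 4 and 5, so that the group had a mean of 8.36 ± 1.48 (SD, n = 5). Peg10, an imprinted gene, was at 12.13 ± 0.23 (SD, n = 4) in EG FCS lines, at 7.18, 10.35, 10.09 and 7.19 in EG 2i lines 1 to 4 and at 7.23, 6.63, 10.38 and 9.75 in EG 2is lines 1 to 4. The EG lines with the higher Peg10 levels in 2i, EG 2i lines 2 and 3 and EG 2is lines 3 and 4, were the female lines with an X dosage of 0.64 or more, the others being male or, for EG 2i line 1, female with an X dosage of −0.04. No test of this was run.

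Nod1 was at 4.38 in EG FCS, 4.56 in EG 2is and 4.5 in EG 2i lines, and at 5.84 ± 0.61 (SD, n = 5) in ES FCS and 6.24 ± 0.81 (SD, n = 5) in ES 2i lines. ES FCS lines 4 and 5 were the most alike of all pairs within a group, with a correlation of 0.998 and 1 gene at least 2-fold apart, beside 12 genes for EG FCS lines 1 and 2, 23 for ES 2i lines 4 and 5 and 532 for ES 2i lines 3 and 4. X dosage was 0.12 in EG FCS line 1, 0.26 and 0.35 in ES FCS lines 1 and 3, and 0.27 and 0.58 in ES 2i lines 1 and 3.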
